A study of Mus musculus with 45 samples.

How the data were processed

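The deposited tables give counts per gene and library, fragment or read counts per the file headers, and FPKM per the file headers. Columns of log2 fold changes and of adjusted p-values of the authors' comparisons were deposited in the same tables, log2 and p-value units per the file headers. Per the submitters' processing notes reads were trimmed with fastp, aligned to GRCm38 with HISAT2 2.2.1, assembled with StringTie 2.2.3, counted with featureCounts 2.0.6 and compared with DESeq2 1.42.0 or edgeR 4.0.16. Cufflinks and GATK 4.6.0.0 are also named there. Per the labels' protocols total RNA was taken with TRIzol from snap-frozen tissue and mRNA was selected with oligo(dT). Conventional and strand-specific libraries are both described and not assigned to samples.

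The 1 incomplete last line of each table was dropped. The fits used the counts of 20 tumor and 25 node libraries. The expression filter of the fits, filterByExpr, left all 7541 tumor genes and all 4364 node genes, except in FLN fits, which tested 4359 or 4360. Another 80 columns of the tumor table and 136 of the node table were not used here. Among the pairs compared, no 2 libraries were copies of each other. The smallest chi-square per gene was 20.8 between libraries of a group and 46.8 between libraries of different conditions in 1 node. Pairs across nodes and tumor pairs across groups were not compared.

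Gene tests used R 4.3.3 and edgeR 4.0.16: TMM factors, that filter, and the quasi-likelihood F-test, with Benjamini-Hochberg adjustment over the held genes and a call under 0.05. The SE of a log2 change was its absolute value over the square root of F. Tumor fits had 1 mean per group and 14 residual degrees of freedom. Node regimen fits held regimen and the day in the label as factors (6 residual degrees of freedom in PLN, 5 in FLN). Trend fits had 1 slope on the log2 of days beside regimen means (8 in PLN, 7 in FLN), and slope differences compared the OD and ICD slopes (5 and 4). The comparison of nodes was blocked by condition (12). YF libraries were compared with 1 control library per node (6 and 5).

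Gene lists (30, of which 24 had at least 3 held genes in a table and were tested) were compared with camera of limma 3.58.1 on log2 CPM with a prior count of 2, at a correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The same was done with an estimated correlation and with fry. A count adjusted over the list alone takes only the p-values of the held members.

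Genes were named by rule: the 6 largest called changes in each direction at a mean of at least 5 CPM, up to 4 members with the smallest p of each called list, and a panel of 14 genes for tumor comparisons with CON, of which 7 were held. Alternatives were DESeq2 1.42.0, RLE factors, a stricter filter (1 CPM in 3 libraries and 50 counts), no filter, limma-trend on log2 of FPKM plus 1, a log2 change of at least 1, only the groups compared, a block by replicate number, the day as a factor or untransformed, fits without YF, no condition block, fits within 1 regimen, and leaving out each library. Added after values were seen were library sizes implied by FPKM, covariates for muscle and nuclear RNA scores, and fits without libraries extreme in either.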

Results

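RNA was sequenced from mouse tumors and lymph nodes to ask how the interval between oxaliplatin (OXA) and a dendritic cell (DC) vaccine changes the response in each tissue. The tumor table held 20 libraries: control (CON, n = 3), DC (n = 4), OXA (n = 3), and OXA followed by DC after 3, 7 or 10 days (OD3, n = 4, OD7, n = 3, OD10, n = 3). The node table held 25 libraries from 2 nodes that the labels abbreviate PLN (13) and FLN (12). PLN gave 4 ICD, 5 OD, 3 YF and 1 YF control library, and FLN gave 4, 4, 3 and 1. ICD and YF are label names whose meaning the labels do not give. The deposited node comparisons name their groups OXA, DC and OD instead. Their log2 changes for DC against OXA had r = 0.999 with YF against ICD in each node, and the next closest pair of regimens r = 0.738 in PLN and 0.841 in FLN, so those comparisons call the ICD libraries OXA and the YF libraries DC. Node labels also give a day of 3, 7, 10 or 14, and each was 1 library, except OD at 14 days in PLN with 2. For OD the day is the interval between OXA and DC, while for ICD and YF the labels do not say what it counts. Node comparisons pooled the days of a regimen. The TNF-α groups and the shorter intervals of the series design were not analysed here. The labels do not say whether libraries of a group came from separate animals, so each tumor p-value measures spread between these samples. Almost every node condition was 1 library, so node p-values rest on residuals from the fitted model rather than on spread between replicates. In the node regimen fits, regimen differences that vary with the day enter those residuals.

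The tumor table held 7541 genes, of which 7416 were protein-coding, and for nodes 4364 were held, of which 4258 were protein-coding. The smallest mean count was 458 in tumor and 1015.8 in node, so both tables, as read here, held only abundant genes. Each ended in an incomplete line, so further genes may exist that were not read. Counts of genes called in the authors' deposited table are likewise counts among the held genes. Transcripts such as Pdcd1, Ifng, Gzmb, Prf1, Cd4, Foxp3 and Tnf were not analysed here. Held counts summed to 16.18 to 17.5 M per tumor library, 12.61 to 14.92 M per FLN library and 11.54 to 16.1 M per PLN library, which is a part of each library. Library sizes implied by the deposited FPKM were 16.72 to 19.04 M, 14.69 to 18.6 M and 15.51 to 20.65 M. Skeletal muscle genes made up 0.00516 to 1.22% of held tumor counts, 0.00262 to 5.43% in PLN and 0.00358 to 0.0107% in FLN. Immunoglobulin genes made up 0.426 to 7.48% of held counts in FLN and 0.533 to 5.49% in PLN.

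Levels below are counts per 1 M held counts (CPM) as mean ± SD, and changes are log2 ± SE. A gene was called at an adjusted p under 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg over the held genes). If no gene changed, a share of about 0.05 of the genes tested would still have an unadjusted p under 0.05. Counts of such genes lay below that share in DC against CON, OD3 against OD7 and OD10 against OD3. They did so too in the trends, the slope differences, the comparisons with the YF control and the tests of regimen changes between nodes. These counts are thus no sign of further changes. Gene lists were tested with camera at a preset correlation of 0.01 between genes, which called 165 of 479 list tests. None of the 165 kept an adjusted p under 0.05 with an estimated correlation, and 6 were also called by fry. List changes below are thus shared shifts of many genes whose joint movement between libraries the preset value understates. Where a list call ended under several alternatives, only some of them are named below. For a list, alternatives below are refits that left out libraries or changed size factors, design or samples, at the preset correlation. They exclude the estimated correlation and fry. DESeq2, limma-trend on FPKM, the log2 change of at least 1 and the day as a factor gave no list test. The filter settings left the list test unchanged by construction.

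The first tumor question was what the vaccine alone did. Interferon-alpha response genes, which report type I interferon signaling, rose as a list in DC tumors, and all 17 held members had a positive change (median 0.61). The list score was 5.54 ± 0.25 log2 CPM in CON (n = 3) and 6.15 ± 0.57 in DC (n = 4). Ifi44 went from 26.4 ± 2.87 to 61.7 ± 51.4 CPM and Ifit1 from 34.5 ± 7.17 to 71.4 ± 56.6 CPM, a mean carried by part of the DC libraries (Ifit1 range 26.9 to 153.7). Camera gave adjusted p = 1.41e-07 for this list, and adjusted p = 0.602 with an estimated correlation. Smaller list shifts were positive for interferon gamma (median 0.43, adjusted p = 0.0022), MHC class I (0.29, 0.00289), the list named M2-like suppressive (0.6, 0.0144) and hypoxia and glycolysis (0.17, 0.00777), and negative for proliferation (-0.11, 0.00198). Each of these also had adjusted p = 0.602 with an estimated correlation. The M2-like list held Arg1, Chil3, Mrc1, Nos2, Spp1, Tgfb1 and Vegfa. Nos2 is not an M2 marker and Vegfa is also in the hypoxia list, so a shift of the list does not by itself show M2 polarization. No gene was called by edgeR, with 282 at an unadjusted p under 0.05 and 0 called by DESeq2. The authors' deposited table also called 0 genes for this comparison.

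Of those 6 lists, interferon alpha kept its call under every such alternative, though it was not called by fry (adjusted p = 0.689). Interferon gamma and MHC class I lost theirs without CON replicate 5 (adjusted p = 0.757) or DC replicate 5 (0.126), the M2-like list without CON replicate 4 (0.134), DC replicate 4 (0.329) or DC replicate 5 (0.108), hypoxia without CON replicate 4 (0.326) or DC replicate 4 (0.498), and proliferation without CON replicate 1 (0.176) or DC replicate 2 (0.203) or with a block by replicate number (0.424).

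OXA alone was compared with CON to isolate the chemotherapy. Hypoxia and glycolysis genes fell as a list, with 13 of 16 held members negative (median -0.57), and 11 members were called when p was adjusted over the list alone against 0 over all genes. Ndrg1, a hypoxia-induced gene, stood at 362.9 ± 22.99 CPM in CON (n = 3) and 177.1 ± 62.9 in OXA (n = 3), Egln3, a prolyl hydroxylase of the hypoxia pathway, at 56.4 ± 18.5 and 23.7 ± 13.8, and the glucose transporter Slc2a1 at 155.8 ± 15.7 and 83.3 ± 24.7. The shift had camera adjusted p = 1.62e-08, fry adjusted p = 0.0336, and adjusted p = 0.355 with an estimated correlation. Proliferation genes rose (27 of 28 positive, median 0.16, adjusted p = 0.000142) and interferon-alpha genes fell (17 of 17 negative, median -0.34, adjusted p = 0.000182), both with adjusted p = 0.676 with an estimated correlation. Endothelial genes rose (Cdh5, Pecam1 and Plvap, median 1.11, adjusted p = 0.0158, 3 called over the list alone), as did the plasma cell list (Sdc1, Xbp1, Edem1 and Txndc5, median 0.23, adjusted p = 0.0488), each with adjusted p = 0.444 with an estimated correlation. The p53 damage list was not called (median 0.15, camera adjusted p = 0.39).

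Skeletal muscle genes were high in part of the OXA tumors. Acta1, the skeletal actin, reached 1543 ± 1478 CPM in OXA (range 6.37 to 2955) against 8.67 ± 7.31 in CON, and Myh4, a fast myosin heavy chain, 1485 ± 2167 (range 2.65 to 3972) against 4.80 ± 4.61. All 11 held muscle genes were positive and called when adjusted over the list alone (camera adjusted p = 1.07e-06), with adjusted p = 0.444 with an estimated correlation. No single gene was called by edgeR (smallest adjusted p 0.0992), while 1189 genes had an unadjusted p under 0.05 and DESeq2 called 197. With a block by replicate number edgeR did call genes. Hypoxia and proliferation kept their list calls under every alternative. Leaving out OXA replicate 2 raised the edgeR count to 529 and ended the interferon-alpha call (adjusted p = 0.251), as did a block by replicate number (0.102), and endothelium was lost without OXA replicate 3 (0.0616) and with a muscle covariate (0.2). The plasma cell list ended without CON replicates 1 (0.0581) or 5 (0.154) or OXA replicates 1 (0.113) or 3 (0.0616), with a muscle covariate (0.174), with the block (0.0958), with RLE factors (0.0504) and with only the groups compared (0.0844). The authors' deposited table called 109 genes up and 140 down, among them Ndrg1 (-1.07, adjusted p = 0.00141) and Egln3 (-1.3, adjusted p = 0.021), and 8 of the 16 hypoxia genes.

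OD3 tumors were compared with CON to see the shortest interval of the combination. Slc6a9, which encodes the glycine transporter 1, rose from 35.8 ± 1.53 CPM in CON (range 34.2 to 37.3, n = 3) to 66.7 ± 8.82 in OD3 (n = 4). It was the only gene called (0.90 ± 0.14, edgeR adjusted p = 0.0392), with 521 genes at an unadjusted p under 0.05 and 33 called by DESeq2. Interferon-gamma genes rose as a list, with 19 of 19 positive (median 0.77, camera adjusted p = 0.000131): Iigp1, an interferon-induced GTPase, stood at 234.0 ± 129.0 CPM in CON and 517 ± 239 in OD3. Antigen presentation rose with it, both MHC class I (17 of 17 positive, median 0.51, adjusted p = 5.78e-05) and class II (8 of 8, median 0.71, adjusted p = 0.00733), and hypoxia and glycolysis rose slightly (0.17, adjusted p = 0.00833). All 4 had adjusted p = 0.845 with an estimated correlation. OD3 replicate 2 did not share the interferon-gamma rise, with a list score of 6.17 log2 CPM. The other OD3 libraries lay at 7.79 to 7.9, and the CON mean was 6.67. Without CON replicate 5, the control lowest in interferon-gamma genes, the interferon-gamma (adjusted p = 0.243), MHC class I (0.0902) and class II (0.443) calls ended, and class II also ended without OD3 replicate 1 (0.0548) and hypoxia without CON replicate 4 (0.297) or OD3 replicate 2 (0.135). The edgeR count was 0 when any 1 of CON replicates 1, 4 or 5 or OD3 replicates 1, 2 or 4 was left out. The authors' deposited table called 66 genes up and 23 down.

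OD7 tumors showed the same gene and more. Slc6a9 stood at 66.9 ± 5.17 CPM (n = 3) against 35.8 ± 1.53 in CON (0.90 ± 0.15, edgeR adjusted p = 0.0355). Ifitm1, an interferon-induced membrane protein gene, fell from 119.6 ± 6.33 CPM (range 112.4 to 124.4) to 43.6 ± 8.39 (range 34.6 to 51.2), a change of -1.45 ± 0.21 (adjusted p = 0.0164, edgeR). Nol8, a nucleolar protein gene, rose from 53.8 ± 2.78 to 77.8 ± 6.94 CPM (0.53 ± 0.09, edgeR adjusted p = 0.0423). Gm13230, chosen after the values were seen, rose from 37.2 ± 4.92 to 63.0 ± 6.75 CPM (0.76 ± 0.13, edgeR adjusted p = 0.0423). These 4 were the only genes called, against 1084 at an unadjusted p under 0.05 and 74 called by DESeq2. A block by replicate number gave a higher edgeR count. Interferon gamma (19 of 19 positive, median 0.86, camera adjusted p = 0.00122), MHC class I (17 of 17, 0.57, adjusted p = 0.000678) and class II (8 of 8, 0.86, adjusted p = 0.0114) rose, each with adjusted p = 0.876 with an estimated correlation. Cd274, which encodes PD-L1, stood at 1.03 ± 0.64 (edgeR adjusted p = 0.447) and Cdkn1a, a p53 target, at 0.71 ± 0.28 (edgeR adjusted p = 0.281), so neither was called. The edgeR count was 0 without CON replicates 1, 4 or 5 or OD7 replicate 3 and 1 without OD7 replicate 1, and the 3 list calls ended without CON replicate 5 (adjusted p = 0.221, 0.108 and 0.25) and class II without OD7 replicate 3 (0.0998). The authors' deposited table called 109 genes up and 93 down. In it Slc6a9 was higher in OD3 (0.91, adjusted p = 4.67e-08) and OD7 (0.87, 6.78e-07), and Ifitm1 lower in OXA (-0.83), OD3 (-0.85), OD7 (-1.48) and OD10 (-0.6), with DC at -0.63 (adjusted p = 0.189, DESeq2 or edgeR per the submitters).

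OD10 was compared with CON for the longest tumor interval. Proliferation genes rose, with 25 of 28 positive (median 0.16, camera adjusted p = 9.55e-05), among them Mcm4, a replication helicase subunit, at 200.1 ± 25.6 CPM in OD10 and 159.3 ± 28.3 in CON, and Top2a, a topoisomerase, at 1175 ± 115 and 977 ± 60.9. Muscle genes rose beside them (11 of 11 positive, median 3.68, adjusted p = 5.36e-05), with Acta1 at 192.4 ± 75.2 CPM in OD10 and 8.67 ± 7.31 in CON. MHC class II (0.75, adjusted p = 0.0144) rose, and endoplasmic reticulum (ER) stress genes (-0.15, adjusted p = 0.0321), including Calr and Ddit3, and hypoxia genes (-0.19, adjusted p = 0.03) fell. These 5 lists had adjusted p = 0.83 with an estimated correlation. MHC class I (0.31, camera adjusted p = 0.0278) had adjusted p = 0.865 with an estimated correlation. The ER stress list, in tumors and nodes, also held danger-signal genes such as Hmgb1 and Anxa1. It shared Xbp1 with the plasma cell list, so shifts of both lists are not independent. No gene was called by edgeR, with 561 at an unadjusted p under 0.05 and 0 called by DESeq2, while the authors' deposited table called 73 up and 85 down. Of the 6 lists, proliferation kept its call under every alternative, and muscle under all but the muscle covariate, which removes that list by construction. Class I ended without CON replicate 5 (0.864) or OD10 replicates 1 (0.825) or 3 (0.0984), class II without CON replicate 5 (0.596) or OD10 replicate 1 (0.207), ER stress without CON replicate 4 (0.295) or OD10 replicate 3 (0.182), and hypoxia without CON replicates 1 (0.148) or 5 (0.22) or OD10 replicate 3 (0.138) or with a block by replicate number (0.345). With a muscle covariate the hypoxia (adjusted p = 0.391), class I (0.254), class II (0.254) and ER stress (0.137) calls ended.

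The 3 intervals were then compared with each other. OD3 against OD7 showed higher proliferation genes in OD3 (27 of 28 positive, median 0.12, camera adjusted p = 2.12e-05) and lower M2-like suppressive genes (6 of 7 negative, median -0.66, adjusted p = 0.0264). Chil3, a marker of alternatively activated macrophages and neutrophils, was called over the list alone, at 4.96 ± 2.95 CPM in OD3 (n = 4) and 382.8 ± 578 in OD7 (n = 3, range 7.03 to 1049), so 1 OD7 library carried most of it. ER stress genes (-0.11, adjusted p = 0.0264) and NF-κB inflammation genes such as Ccl2 and Ccl7 (-0.16, adjusted p = 0.048) were lower in OD3. All 4 had adjusted p = 0.806 with an estimated correlation, and without OD7 replicate 3 all 4 calls ended (proliferation 0.157, M2-like 0.492, ER stress 0.485, NF-κB 0.884). No gene was called by edgeR (271 at an unadjusted p under 0.05, DESeq2 3). The authors' deposited table called 4 genes between these groups, 30 between OD7 and OD10 and 65 between OD3 and OD10.

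OD10 against OD7 showed higher proliferation genes in OD10, with 28 of 28 positive (median 0.21, camera adjusted p = 1.52e-09). Mki67, a marker of cycling cells, stood at 1007 ± 91.4 CPM in OD10 and 767 ± 162 in OD7 (n = 3 each), and Ube2c, which acts in mitotic exit, at 167.6 ± 14.7 and 127.8 ± 18.6. ER stress genes fell (13 of 16 negative, median -0.21, adjusted p = 0.00201), with Trib3, a stress-induced pseudokinase, at 49.5 ± 11.8 and 99.3 ± 43.4 CPM. Hypoxia genes fell (16 of 16 negative, -0.23, adjusted p = 0.000893) and muscle genes rose (1.51, adjusted p = 5.76e-06). These 4 lists had adjusted p = 0.597 with an estimated correlation. Interferon-alpha genes fell (17 of 17 negative, -0.57, camera adjusted p = 5.37e-05, adjusted p = 0.733 with an estimated correlation), as did interferon gamma (-0.55, adjusted p = 0.0323, adjusted p = 0.734 with an estimated correlation). Proliferation, interferon alpha and ER stress kept their calls under every alternative, while hypoxia ended with a muscle covariate (0.0613) and interferon gamma without OD10 replicate 2 (0.697) or OD7 replicates 1 (0.225) or 3 (0.453). No gene was called by edgeR, against 560 at an unadjusted p under 0.05 and 2 called by DESeq2.

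OD10 against OD3 showed lower hypoxia genes in OD10, with 16 of 16 negative (median -0.36, camera adjusted p = 4.93e-11) and adjusted p = 0.119 with an estimated correlation. Bnip3, a hypoxia-induced mitophagy receptor gene, stood at 77.3 ± 12.1 CPM in OD10 (n = 3) and 150.9 ± 39.7 in OD3 (n = 4), and Ldha, lactate dehydrogenase A, at 1015 ± 87.6 and 1279 ± 29.6. This list kept its call under every alternative. Muscle genes were higher in OD10 (Acta1 192.4 ± 75.2 against 0.561 ± 0.368 CPM, 10 called over the list alone, camera adjusted p = 2.93e-15, adjusted p = 0.119 with an estimated correlation). Interferon alpha (-0.46, adjusted p = 0.00094) and interferon gamma (-0.4, 0.0342) were lower and proliferation higher (0.09, 0.00094), each with adjusted p = 0.994 with an estimated correlation, and each ended without 1 or more of the OD3 libraries (interferon alpha without replicate 4, adjusted p = 0.457). In edgeR 0 genes were called, with 242 at an unadjusted p under 0.05 and 14 called by DESeq2.

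The mean of the 3 combinations was compared with OXA to ask what the vaccine added. Hypoxia and glycolysis genes were higher in the combinations, with 13 of 16 positive (median 0.57), 4 called over all genes and 12 over the list alone. Ndrg1 stood at 394.0 ± 87.1 CPM in OD3, 379.1 ± 73.5 in OD7 and 283.6 ± 5.38 in OD10 against 177.1 ± 62.9 in OXA (0.98 ± 0.18, edgeR adjusted p = 0.0139), with CON at 362.9 ± 22.99. Pfkl, a glycolytic phosphofructokinase, stood at 117.9 ± 29.2 CPM in OXA and 227.4 ± 33.1 in OD3 (0.78 ± 0.14, edgeR adjusted p = 0.0139), and Ak4, a mitochondrial adenylate kinase, at 21.4 ± 5.69 and 45.1 ± 5.66 (0.94 ± 0.20, edgeR adjusted p = 0.0349). Egln3 (1.25 ± 0.28, edgeR adjusted p = 0.046), Pgk1 (0.79 ± 0.18, 0.046), Fam162a (0.81 ± 0.18, 0.0472) and Eno1 (0.47 ± 0.10, 0.0401) were also called, as were Egln1 and Gpi1. The list had camera adjusted p = 2.59e-15, fry adjusted p = 0.00301 and adjusted p = 0.0574 with an estimated correlation, and it kept its camera call under every alternative. Eno1 and Pgk1 have near-identical copies elsewhere in the genome, as do Gapdh, Ifitm1, Gm13230, CT010467.1, Tgtp1, Tgtp2, H2 genes and immunoglobulin segments, so how reads divide among copies is uncertain.

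In all 61 genes were called, 16 up and 45 down (837 at an unadjusted p under 0.05, DESeq2 152). With a block by replicate number the count was 8. Cdh5, which encodes the endothelial VE-cadherin, was lower in the combinations, at 42.4 ± 8.92 CPM in OD3, 42.5 ± 7.10 in OD7 and 50.8 ± 6.76 in OD10 against 109.2 ± 34.5 in OXA (-1.28 ± 0.21, edgeR adjusted p = 0.00889), with CON at 51.8 ± 11.4. Its list fell too (median -0.85, camera adjusted p = 0.00218, adjusted p = 0.334 with an estimated correlation). Muscle genes filled much of the list of lower genes, among them Myh4, Actn3, Tnnt3, Ryr1, Ckm, Myl1, Mybpc2, Atp2a1 and Acta1, and 8 of 11 listed muscle genes were called over all genes and 11 over the list alone (camera adjusted p = 2.17e-09, adjusted p = 0.334 with an estimated correlation). Myh4 was 0.193 ± 0.387 CPM in OD3 and 0.778 ± 1.35 in OD7 against 1485 ± 2167 in OXA. Ccng1, a p53 target, fell by 0.57. The p53 damage list was not called, with 8 of 12 held members positive (median 0.07, camera adjusted p = 0.896).

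Immune lists were higher in the combinations than in OXA. Interferon gamma rose (19 of 19 positive, median 0.73, camera adjusted p = 4.41e-10), with Gbp2, a guanylate-binding protein gene, at 771 ± 365 CPM in OD3 and 334.7 ± 402 in OXA, and interferon alpha rose (17 of 17, 0.61, adjusted p = 6.52e-08), both with adjusted p = 0.334 with an estimated correlation. MHC class I rose (0.48, camera adjusted p = 8.65e-07, adjusted p = 0.444 with an estimated correlation), as did MHC class II (0.34, adjusted p = 0.00447), while proliferation fell (-0.14, adjusted p = 5.07e-05), the last 2 with adjusted p = 0.526 with an estimated correlation. All 5 ended without OXA replicate 2 (adjusted p = 0.0522 for interferon gamma, 0.102 for interferon alpha, 0.286 for class I, 0.983 for class II at a median of -0.15, and 0.0522 for proliferation). Without OXA replicate 3, or with a muscle covariate, 0 genes were called, for muscle genes by construction in the last case. The count was 347 without OXA replicate 2, and 28, 29 and 25 without OD10 replicates 1, 2 and 3, 30, 36 and 38 without OD3 replicates 1, 2 and 4, and 33 and 34 without OD7 replicates 1 and 3. The muscle covariate ended the endothelium list call (0.0758). In the authors' deposited table OD3 against OXA gave 95 genes up and 57 down, OD7 38 and 30, and OD10 0 and 1.

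**Figure D1:**
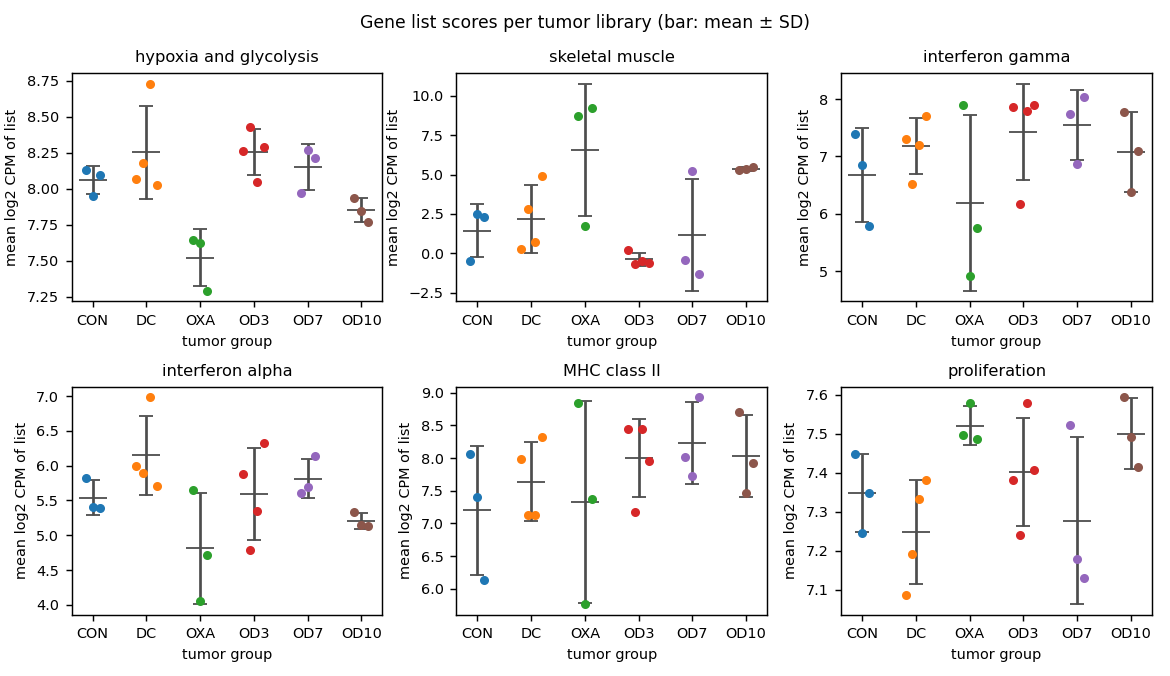
Scores of gene lists (mean log2 CPM of held members, vertical axis) in each tumor library by group. The hypoxia and glycolysis list averaged 7.52 in OXA (n = 3) against 8.06 in CON (n = 3) and 8.26 in OD3 (n = 4).

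**Figure D2:**
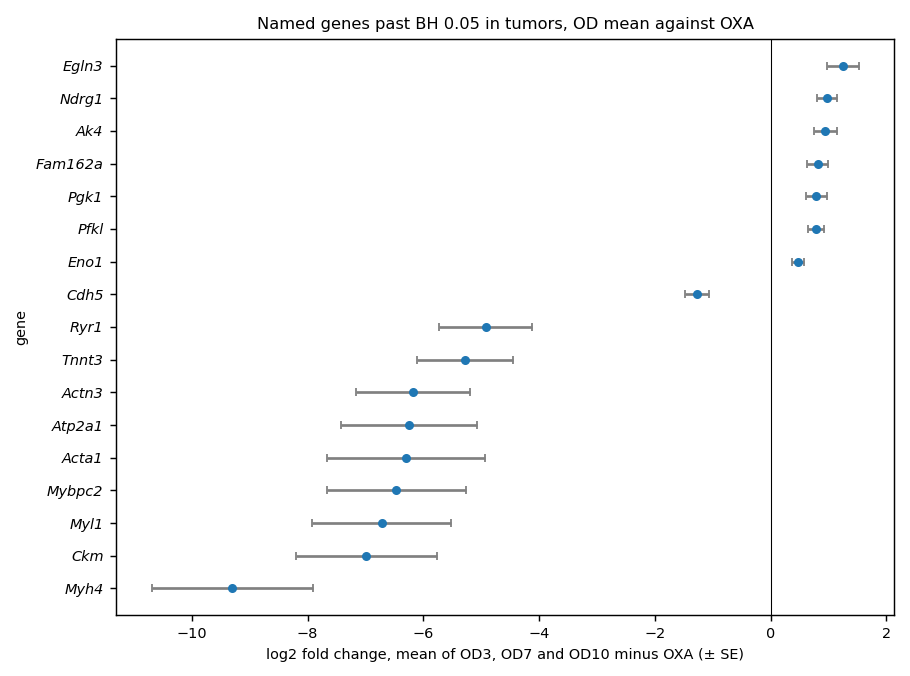
Log2 change ± SE of the combination mean against OXA (horizontal axis) for the named genes that were called (vertical axis). Hypoxia genes such as Ndrg1 (0.98) lie right of 0, and muscle genes lie far left of 0 at a size that depends on the prior count, since some OD3 and OD7 libraries hold 0 counts of them.

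The same mean was compared with DC to ask what OXA added. Interferon-alpha genes were lower in the combinations, with 17 of 17 negative (median -0.5) and 6 called over the list alone against 0 over all genes. Rsad2, an antiviral radical-SAM enzyme gene, stood at 78.0 ± 74.5 CPM in DC (n = 4), 22.7 ± 16.4 in OD3 (n = 4) and 14.3 ± 6.24 in OD10 (n = 3). Proliferation genes were higher (27 of 28 positive, median 0.14, camera adjusted p = 3.63e-07), with Rrm1, a ribonucleotide reductase subunit, at 245.8 ± 19.6 CPM in DC and 312.8 ± 37.0 in OD10. The interferon-alpha list had camera adjusted p = 1.24e-07, and both lists had adjusted p = 0.878 with an estimated correlation and kept their calls under every alternative. ER stress genes were lower (-0.12, adjusted p = 0.00381, adjusted p = 0.878 with an estimated correlation), a call lost without DC replicate 4 (0.191) or OD7 replicate 1 (0.0614), as were hypoxia genes (-0.11, adjusted p = 0.0364, adjusted p = 0.963 with an estimated correlation), lost without DC replicate 4 (0.97) or with a block by replicate number (0.135). CT010467.1, chosen after the values were seen, was the only gene called, at 170.0 ± 20.7 CPM in DC and 93.1 ± 16.2 in OD7 (-0.71 ± 0.11, edgeR adjusted p = 0.0251), with 582 genes at an unadjusted p under 0.05 and 5 called by DESeq2. It was lost (count 0) with a block by replicate number and without DC replicates 3, 4 or 5, OD10 replicates 1 or 3, OD3 replicates 1 or 4, or OD7 replicate 2. The count was 2 without OD7 replicate 1. The authors' deposited table called 19 genes for OD3 against DC, 10 for OD7 and 17 for OD10.

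In the PLN, OD was compared with ICD across shared days. Interferon response genes were lower in OD. The interferon-alpha list fell in 21 of 21 members (median -1.18, camera adjusted p = 6.26e-07) and interferon gamma in 15 of 16 (-0.77, adjusted p = 6.26e-07). Isg15, an interferon-induced ubiquitin-like modifier gene, stood at 28.9 ± 19.8 CPM in OD (n = 5) and 120.4 ± 52.5 in ICD (n = 4), and Cxcl9, a T cell chemokine gene, at 38.9 ± 20.9 and 215.8 ± 235. MHC class I fell in 17 of 17 members (-0.3, adjusted p = 6.41e-05), with 3 called over the list alone and 0 over all genes. Erap1, a peptidase that trims class I peptides, stood at 133.4 ± 13.6 CPM in OD and 176.7 ± 26.7 in ICD. Genes of the CD8 list such as Cd8b1 and Cd3d (-0.46, adjusted p = 0.0129) and mature dendritic cell genes such as Ccl22 and Fscn1 (-0.36, adjusted p = 0.0285) fell. In nodes, here and below, the CD8 list held Ccl5, Cd2, Cd3d, Cd3e, Cd3g, Cd8a, Cd8b1 and Ctsw. Several of these are T cell genes not particular to CD8 cells, and Ccl5 is also in the mature dendritic cell list. All 5 lists had adjusted p = 0.876 with an estimated correlation. The interferon and class I lists kept their calls under every alternative, whereas the CD8 list ended without OD10 (0.395), ICD d3 (0.0859) or ICD d10 (0.217) and the dendritic cell list without OD10 (0.579), OD3 (0.0637), ICD d3 (0.095) or ICD d10 (0.367). Single genes did not pass edgeR (smallest adjusted p 0.164), against 677 at an unadjusted p under 0.05, 343 called by DESeq2 and 2 in the authors' deposited table. Of the 4 ICD libraries 3 (d3, d7 and d14) were low in nuclear RNA and 0 of the 5 OD libraries were, so this comparison also sets libraries low and not low in nuclear RNA against each other. Without the low libraries ICD is 1 library. Regimens may also differ by handling batch, which the labels do not give, and in the PLN 1 OD library, OD10, held 10850 CPM of Acta1.

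The YF regimen was compared with OD and ICD in the PLN. Naive T cell genes were higher in YF than OD in 11 of 11 members (median 0.49, camera adjusted p = 0.000611, adjusted p = 0.839 with an estimated correlation), a call kept under every alternative. Tcf7, a transcription factor of naive T cells, stood at 460.8 ± 50.8 CPM in YF (n = 3) and 310.6 ± 109 in OD (n = 5), and S1pr1, a node egress receptor gene, at 334.6 ± 42.8 and 245.0 ± 61.8. B cell genes (0.36, adjusted p = 0.00349) and interferon gamma (0.25, adjusted p = 0.0286) were higher, and neutrophil genes such as S100a8 (-2.43, adjusted p = 0.0384) and adipocyte genes such as Fabp4 (-4.29, adjusted p = 0.0451) lower, all with adjusted p = 0.839 with an estimated correlation. Without OD10 the B cell (0.961), neutrophil (0.425) and adipocyte (0.425) calls ended, and without OD7 interferon gamma (0.67) did. Of the 3 YF libraries 1 (d7) and of the 5 OD libraries 0 were low in nuclear RNA. A nuclear RNA covariate ended the interferon gamma (0.0876), neutrophil (0.128) and adipocyte (0.143) calls. Gene-level calls by edgeR numbered 0 (372 at an unadjusted p under 0.05, DESeq2 117, and 1 in the authors' deposited table). The nuclear RNA covariate raised the edgeR count.

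Against ICD, YF in the PLN had lower interferon alpha (21 of 21 negative, median -0.94, camera adjusted p = 9.48e-05), interferon gamma (-0.54, adjusted p = 0.0211), MHC class I (-0.38, adjusted p = 0.000349) and ER stress genes (10 of 10 negative, -0.51, adjusted p = 0.0053), all with adjusted p = 0.798 with an estimated correlation. Psme2, a proteasome activator subunit, stood at 130.9 ± 13.6 CPM in YF (n = 3) and 208.7 ± 44.6 in ICD (n = 4), and Isg15 at 55.4 ± 49.2 and 120.4 ± 52.5. None of the 4 lists kept its call throughout: without ICD d10 interferon alpha (0.112), interferon gamma (0.165) and class I (0.0757) ended, without YF d10 interferon alpha (0.389) and interferon gamma (0.508), and without YF d7 ER stress (0.076). Of the 4 ICD libraries 3 (d3, d7 and d14) and of the 3 YF libraries 1 (d7) were low in nuclear RNA, and ER stress also ended with a nuclear RNA covariate (0.248). Without the low libraries ICD is 1 library. The edgeR count of called genes was 0, with 396 at an unadjusted p under 0.05 and 5 called by DESeq2, and the authors' deposited table called 12 up and 3 down.

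YF libraries were also set against the single YF control of each node. Spread in these fits comes from the other libraries, and the lone control is assumed to vary like them, so the p-values do not measure variation between controls. A library that is unusual by itself would give the same shifts. In the PLN, proliferation genes were higher in 17 of 17 members (median 1.14, camera adjusted p = 6.49e-23, adjusted p = 0.688 with an estimated correlation), 16 of them called over the list alone and 0 over all genes. Top2a stood at 367.3 ± 56.5 CPM in YF (n = 3) and 110.9 in the control (n = 1), and Tpx2, a spindle assembly factor, at 91.3 ± 21.8 and 25.8. Interferon alpha (21 of 21 positive, 1.93, adjusted p = 4.31e-08), interferon gamma (0.67, 0.000306), MHC class I (0.31, 0.00657) and ER stress genes (0.55, 0.00551) were higher and endothelial genes lower (-0.65, 0.0042), all with adjusted p = 0.731 with an estimated correlation. The interferon-alpha score was 4.94 in the control and 7.01, 7.72 and 4.79 at YF d3, d7 and d10, so 1 day lay below the control. Proliferation, interferon alpha and endothelium kept their calls, while ER stress ended without YF d10 (0.0841), class I without YF d7 (0.0883) and interferon gamma without the libraries low in nuclear RNA (0.0785). The endothelial gene Egfl7 stood at 57.2 ± 6.44 CPM against 115.5 in the control. By edgeR, 0 genes were called (106 at an unadjusted p under 0.05, DESeq2 7, and 15 in the authors' deposited table), and the single control cannot be left out. That control also held 178.7 CPM of Acta1.

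In the FLN the same contrast, again with 1 control library, gave interferon alpha higher in 21 of 21 members (median 2.2, camera adjusted p = 1.04e-15, adjusted p = 0.428 with an estimated correlation) and MHC class I in 17 of 17 (0.47, adjusted p = 1.04e-15, adjusted p = 0.335 with an estimated correlation). Isg15 stood at 138.5 ± 188 CPM in YF (range 10.0 to 354.3, n = 3) and 9.13 in the control, so 1 day carried much of it. The interferon-alpha score was 5.22 in the control and 5.26 at YF d10, against 8.91 at YF d7. Interferon gamma (1.24, adjusted p = 1.36e-13), mature dendritic cell genes (0.46, 1.48e-05) and endothelium (-0.29, 0.0075) had adjusted p = 0.41 with an estimated correlation. Matrix genes fell (-0.47, camera adjusted p = 0.00133, adjusted p = 0.428 with an estimated correlation), and proliferation (0.32, 0.000684), CD8 T cell genes (0.2, 0.0248) and ER stress genes (0.3, 0.0124) rose with adjusted p = 0.674 with an estimated correlation. Of the 9 lists 6 kept their call under every alternative, while CD8 (0.639) and endothelium (0.349) ended without YF d10 and ER stress without YF d7 (0.0546). At the gene level edgeR called 0 (31 at an unadjusted p under 0.05, DESeq2 4, and 2 in the authors' deposited table). In both nodes YF d7 was low in nuclear RNA and the control was not.

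OD against ICD in the FLN showed more B cell transcript in OD. B cell genes were higher in 14 of 14 members (median 0.4, camera adjusted p = 0.000714), 5 of them called over the list alone and 0 over all genes. Cd37, a B cell tetraspanin gene, stood at 989.5 ± 191 CPM in OD and 516.6 ± 86.0 in ICD (n = 4 each), and Fcer2a, the CD23 gene, at 656.0 ± 182 and 307.3 ± 49.6. Fibroblast and matrix genes were lower in 9 of 9 members (-0.58, adjusted p = 0.000714, 3 called over the list alone), with Col3a1, a fibrillar collagen gene, at 178.8 ± 60.5 and 422.5 ± 212. MHC class II (0.39, adjusted p = 0.00619) and adipocyte genes (2.36, 0.0213) were higher, and plasma cell (-0.75, 0.0213), ER stress (-0.47, 0.00619) and proliferation genes (-0.34, 0.000868) lower. All 7 lists had adjusted p = 0.652 with an estimated correlation. Of the 4 ICD libraries 3 were low in nuclear RNA and 0 of the 4 OD libraries were, and without the low libraries ICD is 1 library, where proliferation ended (0.549). B cell and matrix kept their calls under every alternative, and the others ended without ICD d7 (plasma cell 0.136, adipocyte 0.0691, ER stress 0.0747, proliferation 0.0545) or ICD d10 (class II 0.059). Called genes numbered 0 by edgeR (smallest adjusted p 0.25), against 803 at an unadjusted p under 0.05, 312 called by DESeq2 and 67 in the authors' deposited table, and 202 genes were called without YF d7 and 2 without ICD d7.

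YF against OD in the FLN called 12 lists, the most of the 6 regimen comparisons. Ccl5, a chemokine gene expressed by activated T cells, stood at 235.1 ± 5.87 CPM in YF (range 229.1 to 240.8, n = 3) and 92.6 ± 0.667 in OD (range 91.8 to 93.2, n = 4), a change of 1.39 ± 0.17 (edgeR adjusted p = 0.041). T cell transcripts rose with it. The CD8 list, which includes Ccl5, rose in 8 of 8 members (median 0.83, camera adjusted p = 1.75e-07, 7 called over the list alone and 1, Ccl5, over all genes), with Cd8a at 419.6 ± 103 and 226.7 ± 31.0 CPM. The naive T cell list rose too (0.49, adjusted p = 5.72e-05), with Il7r, the IL-7 receptor gene, at 339.4 ± 76.0 and 130.8 ± 28.3. Mature dendritic cell genes rose (0.57, adjusted p = 0.000459), with Fscn1, an actin bundler of mature dendritic cells, at 587.4 ± 45.2 and 260.9 ± 37.8. Proliferation fell in 17 of 17 members (-0.84, adjusted p = 2.96e-12, 16 called over the list alone), plasma cell genes in 6 of 6 (-1.25, adjusted p = 5.72e-05), germinal centre genes in 5 of 5 (-0.78, adjusted p = 0.00739), ER stress genes in 10 of 10 (-0.59, adjusted p = 0.000131), and adipocyte genes (-2.63, adjusted p = 0.00315), while endothelium rose (0.46, adjusted p = 0.00739). These 9 lists had adjusted p = 0.298 with an estimated correlation.

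B cell genes (14 of 14 negative, -0.48, camera adjusted p = 5.72e-05) and MHC class II (-0.47, adjusted p = 0.00145) fell in the same comparison with adjusted p = 0.428 with an estimated correlation, and interferon gamma rose (0.57, adjusted p = 0.0108, adjusted p = 0.646 with an estimated correlation). The germinal centre list held 5 of its 14 genes (Bcl6, Cd38, Cxcr5, Mybl1 and Pou2af1). Its fall was not separated from that of B cell genes. Mybl1, a germinal centre transcription factor gene, stood at 13.3 ± 6.14 CPM in YF and 121.2 ± 47.9 in OD. Jchain, the antibody joining chain gene, stood at 142.6 ± 118 and 2005 ± 1353 CPM. Ighv3-1, an antibody heavy-chain segment chosen after the values were seen, was the other called gene (-4.21 ± 0.31, edgeR adjusted p = 0.00164), at 1.93 ± 0.234 and 31.2 ± 16.2 CPM. Of the 12 lists 10 kept their call under every alternative. Interferon gamma ended without OD3 (0.115), OD7 (0.0921) or YF d7 (0.489), and endothelium without the libraries low in nuclear RNA (0.055). Beside the 2 called genes, 670 had an unadjusted p under 0.05, DESeq2 called 313, and 150 were called in the authors' deposited table. Of the 3 YF libraries 1 (d7) and of the 4 OD libraries 0 were low in nuclear RNA. The edgeR count was 1 without OD10, OD14, ICD d10, ICD d14, YF d3, YF d7 or YF d10, 4 without OD7 or ICD d7 and 6 without ICD d3.

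YF against ICD in the FLN showed lower transcripts of DNA replication and antibody secretion genes in YF, in a gene count that relabelled groups matched or passed in 3 of 35 splits, the real one included. Rrm2, a ribonucleotide reductase subunit, stood at 43.9 ± 9.35 CPM in YF (n = 3) and 179.0 ± 56.0 in ICD (n = 4) (-2.16 ± 0.26, edgeR adjusted p = 0.0338), Pclaf, a PCNA-binding factor, at 52.0 ± 18.6 and 225.1 ± 59.2 (-2.14 ± 0.26, 0.0338), and the cyclin gene Ccna2 changed by -1.91 ± 0.26 (edgeR adjusted p = 0.0393). Mzb1, a chaperone of antibody-secreting cells, stood at 52.2 ± 6.56 and 490.7 ± 328 CPM (-3.44 ± 0.49, edgeR adjusted p = 0.049), Ell2, which drives antibody secretion transcripts, at 45.5 ± 2.33 and 181.2 ± 67.5 (-2.12 ± 0.32, 0.049), and Manf, an ER stress protein gene, at 91.3 ± 15.7 and 331.9 ± 153 (-1.98 ± 0.31, 0.0494). Slpi, a protease inhibitor gene, stood at 7.96 ± 6.41 and 1403 ± 1026 CPM (-8.19 ± 1.27, edgeR adjusted p = 0.049). Kpna2, Hells, Psat1, Ighe, Igkv8-19 and Ighv3-1 were also lower. Ccl5 was the only gene higher in YF (1.12 ± 0.17, edgeR adjusted p = 0.049), at 235.1 ± 5.87 and 113.9 ± 25.7 CPM. In all 14 genes were called, 1 up and 13 down, with 889 at an unadjusted p under 0.05 and 587 called by DESeq2. The authors' deposited table called 42 up and 171 down, with Rrm2 at -2.04, Pclaf at -2.12, Slpi at -7.49 and Ccl5 at 1.01.

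The lists moved with these genes. Proliferation fell in 17 of 17 members (median -1.2, camera adjusted p = 1.48e-16), ER stress in 10 of 10 (-0.8, adjusted p = 1.24e-07), plasma cell genes in 6 of 6 (-1.93, adjusted p = 6.48e-07) and p53 damage genes such as Trp53inp1 and Ccng1 in 4 of 4 (-0.52, adjusted p = 0.0109), with adjusted p = 0.305 with an estimated correlation and fry adjusted p = 0.0303 for each. CD8 T cell genes (0.71, adjusted p = 8.16e-05), mature dendritic cell genes (0.63, 0.0018) and NF-κB inflammation genes such as Relb (0.43, 0.00253) rose and matrix genes fell (-0.68, 0.00147), with adjusted p = 0.353 with an estimated correlation, and naive T cell genes rose (0.65, camera adjusted p = 0.00102, adjusted p = 0.42 with an estimated correlation). Of the 9 lists 6 kept their calls, while p53 damage ended without ICD d10 (0.0525) or YF d7 (0.101), NF-κB without ICD d10 (0.0525) and dendritic cell genes without YF d7 (0.109). The gene count was 1 without OD10, OD14, ICD d10, ICD d14, YF d3 or YF d10, 2 without ICD d7, 23 without OD3, 40 without OD7, 65 without ICD d3 and 439 without YF d7. Library sizes implied by FPKM gave 47 genes, RLE factors 6, DESeq2 587 and a nuclear RNA covariate 1. In these 4 ICD and 3 YF libraries, ICD d3, d7 and d14 and YF d7 were low in nuclear RNA.

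**Figure D3:**
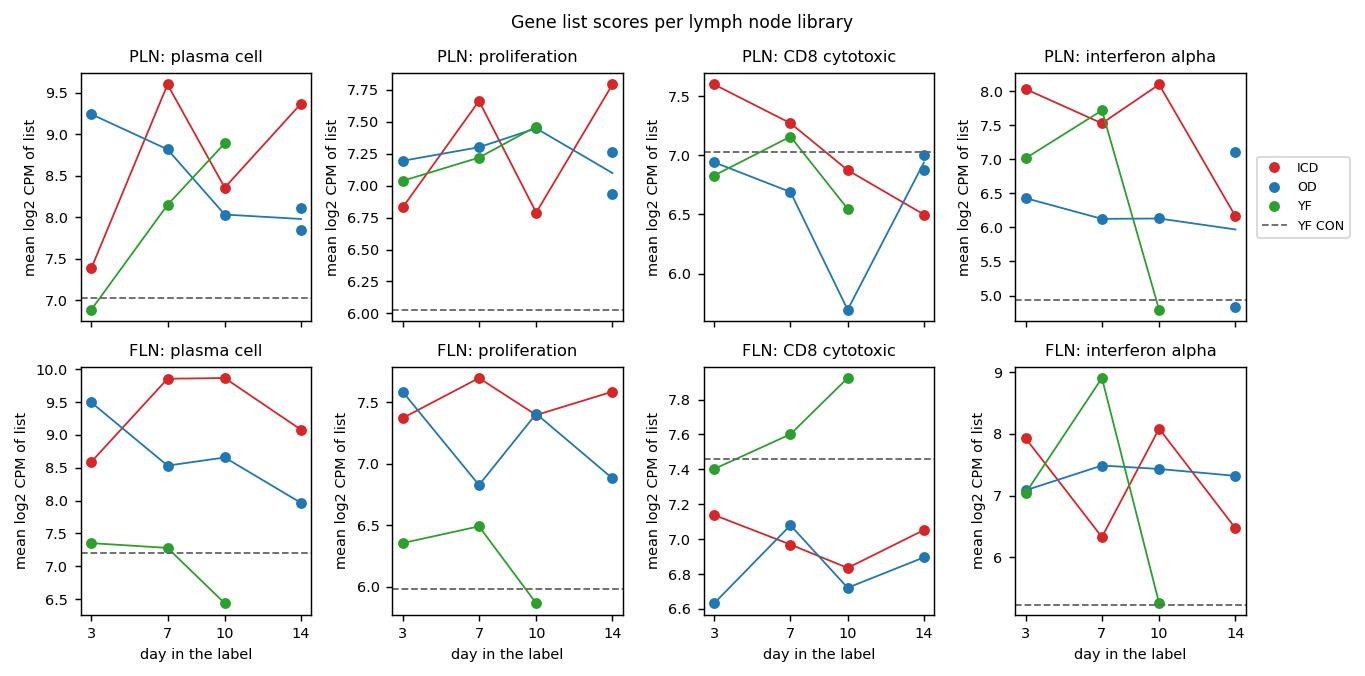
Scores of gene lists (mean log2 CPM of held members, vertical axis) in each node library by the day in its label (horizontal axis), regimen and node, with the YF control as a dashed line. In the FLN the plasma cell list averaged 7.02 in YF (n = 3), 8.66 in OD (n = 4) and 9.35 in ICD (n = 4).

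The trend fits asked whether nodes change with the day in the label, per doubling, over OD, ICD and YF together. That day is known to be an interval between treatments only for OD, so the shared slope is not a test of that interval. In the PLN, interferon alpha fell in 21 of 21 members (median -0.27, camera adjusted p = 4.65e-11), MHC class I fell (-0.13, adjusted p = 2.97e-07), mature dendritic cell genes fell (-0.15, adjusted p = 0.000224), with Ccl22, a dendritic cell chemokine gene, at -0.35 ± 0.20 per doubling, and proliferation rose in 17 of 17 members (0.13, adjusted p = 4.01e-07), with Cenpe, a kinetochore motor gene, at 0.29 ± 0.12. Those 4 kept their calls under every alternative. CD8 (-0.22, 0.000117), naive T cell (-0.12, 0.0016), interferon gamma (-0.16, 0.000152) and NF-κB genes (-0.13, 0.00132) fell and ER stress genes rose (0.09, 0.00781). All 9 lists had adjusted p = 0.56 with an estimated correlation. Interferon gamma ended without YF d10 (0.112), NF-κB without ICD d3 (0.114) and ER stress without YF d3 (0.356), YF d10 (0.0758), ICD d3 (0.781) or ICD d14 (0.353). Without the libraries low in nuclear RNA the CD8 (0.114), naive T cell (0.138), NF-κB (0.13) and ER stress (0.638) calls ended. In edgeR 0 genes were called (44 of 4364 at an unadjusted p under 0.05, below the share of 0.05 due by chance, DESeq2 0).

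In the FLN the slope was downward for endothelial, matrix and macrophage lists, while lymph node stroma was not called (camera adjusted p = 0.513). Endothelial genes fell in 5 of 5 members (median -0.25, camera adjusted p = 1e-05, adjusted p = 0.176 with an estimated correlation), with Cdh5 at -0.29 ± 0.10 per doubling, matrix genes in 8 of 9 (-0.26, adjusted p = 1.43e-06, adjusted p = 0.294 with an estimated correlation), with Col3a1 at -0.36 ± 0.15, and macrophage genes in 6 of 6 (-0.2, adjusted p = 3.9e-05, adjusted p = 0.513 with an estimated correlation), with Apoe at -0.26 ± 0.12. These 3 kept their calls under every alternative. Proliferation (-0.12, adjusted p = 1.2e-05), interferon alpha (-0.1, 0.00134) and plasma cell genes (-0.2, 0.0249) fell with adjusted p = 0.73 with an estimated correlation, and without OD3 proliferation (0.312) and plasma cell genes (0.688) ended, as did interferon alpha without ICD d3 (0.384), ICD d14 (0.345) or YF d10 (0.419). Single genes did not pass edgeR (61 at an unadjusted p under 0.05, DESeq2 0).

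The last question was whether the slope on this day differed between OD and ICD. Since the day may count different things in the 2 regimens, a difference is not one of equal intervals. In each node ICD d3, d7 and d14 were low in nuclear RNA and no OD library was, so libraries low and not low are also compared. Without the low libraries ICD is 1 library and has no slope, so that alternative could not be run. In the PLN, the slope of CD8 genes was higher in OD than in ICD in 8 of 8 members (median difference 0.37 per doubling, camera adjusted p = 0.00202, adjusted p = 0.603 with an estimated correlation) and that of neutrophil genes lower in 5 of 5 (-3.38, adjusted p = 1.02e-05, adjusted p = 0.6 with an estimated correlation), and only these 2 of 13 lists kept their calls. The CD8 list score in ICD was 7.60, 7.27, 6.87 and 6.50 at days 3, 7, 10 and 14, and in OD 6.94, 6.69, 5.70, and 6.88 and 7.00 in the 2 libraries of day 14, so OD10 was the lowest. The neutrophil score was 1.06, 2.32, 9.73 and 7.34 in ICD and 6.81, 6.49, 11.08, and 2.79 and 5.53 in OD, highest at day 10 in both, so neither course ran one way. Ngp, a neutrophil granule gene, ranged from 5.39 to 3199 CPM over the OD libraries. Plasma cell genes (-1.15, adjusted p = 9.74e-11, adjusted p = 0.579 with an estimated correlation) had Jchain at -3.0 ± 1.11 and ended without ICD d3 (0.122). ER stress (-0.55, camera adjusted p = 1.96e-07, adjusted p = 0.6 with an estimated correlation) ended without ICD d3 (0.0653). Proliferation (-0.35, 9.43e-06), interferon gamma (0.47, 2.1e-05), MHC class I (0.18, 0.000543), macrophage (-0.48, 0.00435), matrix (-0.47, 0.0164) and NF-κB genes (0.19, 0.0245) had adjusted p = 0.603 with an estimated correlation. Naive T cell (0.24, 0.0157) and mature dendritic cell genes (0.27, 0.035) had adjusted p = 0.618 with an estimated correlation, and interferon alpha (0.5, 0.00435) adjusted p = 0.649 with an estimated correlation. Each of these 9 ended without at least 1 library. Gene-level calls by edgeR numbered 0 (65 at an unadjusted p under 0.05, DESeq2 13), with 3 genes without ICD d7 and 1 without OD10.

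In the FLN, the slope of B cell genes was higher in OD than in ICD in 14 of 14 members (median difference 0.42, camera adjusted p = 1.1e-13), with Cr2, the complement receptor 2 gene, at 0.79 ± 0.19 per doubling, and that of neutrophil genes lower in 5 of 5 (-2.19, adjusted p = 1.05e-05). The B cell score was 8.65, 9.08, 9.25 and 9.33 at days 3, 7, 10 and 14 in OD and 8.62, 8.92, 8.55 and 8.30 in ICD. The neutrophil score was 6.18, 4.45, 7.88 and 3.57 in OD and 3.15, 2.65, 7.82 and 7.49 in ICD. These 2 of 17 lists kept their calls under every alternative run, which did not include leaving out the libraries low in nuclear RNA. Plasma cell (-1.0, 2.34e-08), interferon gamma (0.34, 9.17e-08), interferon alpha (0.52, 1.4e-07), proliferation (-0.32, 1.25e-06), ER stress (-0.53, 1.05e-05), macrophage (-0.36, 0.00152), MHC class II (0.14, 0.0058), MHC class I (0.14, 0.00639), CD8 (0.16, 0.0164), lymph node stroma (0.16, 0.025), NF-κB (0.17, 0.0259) and type 1 dendritic cell genes such as Naaa (-0.12, 0.0464) were also called. All 14 had adjusted p = 0.37 with an estimated correlation. Skeletal muscle (camera adjusted p = 0.0431, adjusted p = 0.37 with an estimated correlation) was called down at a median of 0.01, so test and median differ in sign. Naive T cell genes (0.19, 0.0293) had adjusted p = 0.431 with an estimated correlation and matrix genes (-0.3, 0.0396) adjusted p = 0.421 with an estimated correlation. Without ICD d3 the plasma cell (0.854), interferon gamma (0.836), interferon alpha (0.936), proliferation (0.441) and ER stress (0.996) calls ended. The edgeR count of called genes was 0 (smallest adjusted p 0.0695, 105 at an unadjusted p under 0.05, DESeq2 16), with 4 genes without ICD d7 and 1 without ICD d3.

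The 2 nodes were compared within the 12 shared conditions. Muscle transcript set them apart: Acta1 (edgeR adjusted p = 0.00337), Ckm (0.0188) and Myh4 (0.0486) were the 3 called genes, all lower in FLN. Myh4 was 0 CPM in every FLN library and 19390 CPM in PLN OD10, 543.2 in PLN ICD d3 and 232.3 in the PLN YF control, and Acta1 was 10850 CPM and Ckm 4266 CPM in PLN OD10. Immune lists were higher in FLN: MHC class I in 17 of 17 members (median 0.24, camera adjusted p = 2.41e-14), interferon gamma in 15 of 16 (0.37, adjusted p = 1.77e-11), mature dendritic cell genes (0.29, 1.61e-06) and NF-κB genes (0.18, 3.87e-05), with skeletal muscle lower (9 of 9 negative, 2.94e-08), all with adjusted p = 0.27 with an estimated correlation. Nlrc5, the class I transactivator gene, stood at 476.6 ± 43.4 CPM in FLN OD (n = 4) and 317.6 ± 78.6 in PLN OD (n = 5). Interferon alpha (0.44, camera adjusted p = 3.61e-12) and CD8 genes (0.23, 2.51e-05) had adjusted p = 0.306 with an estimated correlation, naive T cell (0.12, 0.00578) and macrophage genes (0.26, 0.0028) 0.416, and proliferation (-0.21, 2.63e-05) and matrix genes (-0.22, 0.0459) adjusted p = 0.454 with an estimated correlation.

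None of these 11 node lists kept its call under every alternative. Within ICD the interferon-alpha change was -0.23 (adjusted p = 1.36e-06) and proliferation 0.22 (adjusted p = 2.75e-10), both reversed, and the MHC class I (0.476), interferon gamma (0.176), CD8 (0.338), dendritic cell (0.894) and NF-κB (0.801) calls ended. The 3 genes were lost without PLN OD10, without the condition block, within each regimen and without the conditions high in muscle. A test of whether regimen changes differ between nodes called 0 genes by edgeR for OD against ICD, YF against OD and YF against ICD (unadjusted p under 0.05 in 11, 207 and 136 genes).

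**Figure D4:**
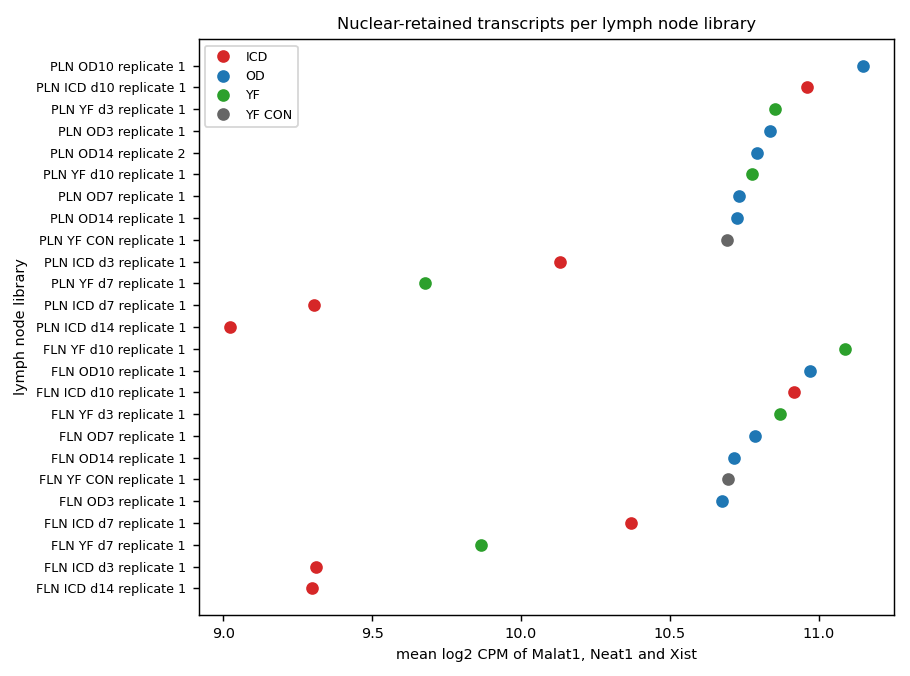
Mean log2 CPM of Malat1, Neat1 and Xist (horizontal axis) in each of the 25 node libraries (vertical axis), colored by regimen. The score lies between 9.02 and 10.4 in 8 libraries and between 10.7 and 11.1 in the other 17.

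Gene positions in GRCm38 were, by chromosome: Slc6a9 (ENSMUSG00000028542) 4, 117834506 to 117875198, Ifitm1 (ENSMUSG00000025491) 7, 140967221 to 140969825, Nol8 (ENSMUSG00000021392) 13, 49653078 to 49679016, Ndrg1 (ENSMUSG00000005125) 15, 66929318 to 66969640, Pfkl (ENSMUSG00000020277) 10, 77986947 to 78010083, Egln3 (ENSMUSG00000035105) 12, 54178981 to 54203860, Cdh5 (ENSMUSG00000031871) 8, 104101625 to 104144511, Ccl5 (ENSMUSG00000035042) 11, 83525778 to 83530518, Rrm2 (ENSMUSG00000020649) 12, 24708241 to 24714146, Pclaf (ENSMUSG00000040204) 9, 65890237 to 65903266, and Mzb1 (ENSMUSG00000024353) 18, 35647266 to 35649367. A self-test that planted known changes recovered 32.8% of genes at a log2 change of 0.5 and 88.1% at 1 for OXA against CON, and 0% and 55.2% for FLN YF against ICD. At 0.5 the other comparisons tried gave 59.7% (OD mean against OXA), 4.5% (PLN OD against ICD) and 85.1% (FLN against PLN), so how much a count of 0 says about small changes differs between comparisons. The FLN trend gave 62.7%, but there 0.5 was a change per doubling of days, so that share is not comparable. Counts were drawn for each gene alone, without the joint movement of genes in the real libraries. The interferon-gamma list, planted at 0.5, was missed by camera in OXA against CON (adjusted p = 0.476), where 1 other list was called. Camera called it in the other comparisons tried, with 1 other list called in FLN against PLN.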

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

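The tests of this part were chosen after the results were seen, except the GC and length correction, which was set before. A screen for a single library far from its group took 50 list and gene values in the tumor groups DC and OD3 and found 5. Other tumor groups and the nodes were not screened, and no adjustment was made for the number of values. The ER stress list in DC replicate 5 was 7.42 log2 CPM (others 7.63 to 7.65, gap share 0.897). OD3 replicate 2 gave the other 4: mature dendritic cell genes 5.51 (others 6 to 6.05, 0.899), the interferon-gamma list 6.17 (7.79 to 7.9, 0.937), Cxcl9 6.23 (8.16 to 8.39, 0.896) and Cxcl10 5.28 (6.97 to 7.09, 0.934). All libraries were kept.

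Low Malat1, Neat1 and Xist marked 8 node libraries: ICD d3, d7 and d14 and YF d7 in both nodes (scores 9.023 to 10.369, other 17 at 10.676 to 11.148), a set first drawn at the largest gap (4 libraries) and widened after scores were seen. After the trend with GC and length was removed, the median difference of the 3 was -1.15, against -1.33 before (SD over genes 0.296). Malat1 went from -1.33 to -1.40, Neat1 from -1.53 to -1.15 and Xist from -0.79 to -0.66. That trend was thus not the whole cause, while a contribution to Neat1 and Xist stays open. ICD treatment as the whole cause was ruled out by scores, with ICD d10 (10.959 and 10.916) among the high libraries and YF d7 (9.678 and 9.864) below all 17, 4 of 4 on the other side (2 of 4 in the set first drawn), while an ICD effect on some days stays open. Fewer counts as the whole cause were tested in a form reset more than once after its first form gave an undecided 3, so its outcome alone decides nothing. Of the 17 others, none of them low in the 3 transcripts, 17 by held counts lay below the median of the 8. By sizes implied by FPKM 8 did (median 17.455 M), and 4 of the 8 lay below the others' median. Held counts, a part of each library, thus argue against fewer counts as the whole cause, while FPKM sizes do not separate the sets. A handling batch stays open, since 12 of 12 conditions had both nodes on 1 side (10 in the set first drawn), and a batch and a condition effect cannot be told apart.

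Skeletal muscle genes in tumors were highest in OXA replicates 1 and 3, with 10 of 11 genes having their 2 highest libraries there. These libraries had been seen to be highest, so the count decides nothing, and muscle tissue in the sample stays open. Oxaliplatin as the whole cause was not met, since 6 of 13 OXA and OD libraries lay above the highest CON score (2.47). Dilution by muscle RNA as the reason for the lower hypoxia list in OXA would lower all other genes alike. On library sizes implied by FPKM the hypoxia list differed from CON by a median of -0.62 and the other 7514 genes outside the muscle list by -0.03 (SD 0.37), so dilution alone was ruled out.

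Relabelled groups were fitted to see how many genes arise without the real labels. OD3 against CON called 1 gene, at most 0 in other splits (1 of 35 as large), OD7 against CON 4 and 0 (1 of 10, too few for a judgement), the OD mean against OXA 61 and 175 (3 of 100 as large), and against DC 1 and 20 (3 of 100). FLN YF against OD called 2 and at most 1 (1 of 35), FLN YF against ICD 14 and 29 (3 of 35), so chance is not excluded there, and FLN against PLN 3 and 5 (4 of 100). With 0 called genes every split is as large as the real one: 35 of 35 in DC against CON, OD3 against OD7 (highest other 1), OD10 against OD3, PLN YF against ICD (233), FLN OD against ICD (1) and the FLN slope difference (3), 10 of 10 in OXA against CON, OD10 against CON and OD10 against OD7 (too few for a judgement), 56 of 56 in PLN YF against OD (39), and 100 of 100 in PLN OD against ICD (515) and the PLN slope difference (242). Why other splits gave more genes was not tested.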

How the results depend on the processing

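Settings with muscle, nuclear RNA and FPKM library sizes were chosen after the results were seen, and the cause of each difference was not tested. Tumor replicates sharing a number were not treated as paired, since the labels do not say whether the numbers pair them. Over deviations from group means, 34 such pairs had r from -0.35 to 0.579 (median 0.067, other pairs -0.006). Of these 34, 16 had r over 0.1, so pairing or a shared batch stays open. A replicate block gave 60 called genes for OXA against CON, 40 for OD7 against CON, 8 for the OD mean against OXA and 0 against DC.

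DESeq2 called 197 (OXA against CON), 33 (OD3), 74 (OD7), 3 (OD3 against OD7), 2 (OD10 against OD7), 14 (OD10 against OD3), 152 (OD mean against OXA), 5 (against DC), and in nodes 343, 117, 5, 13 and 7 (PLN OD against ICD, YF against OD, YF against ICD, slope difference, YF against control), 312, 313, 587, 16 and 4 (FLN, same order), and 7 (FLN against PLN). With only the groups compared the counts were 14 (OD3 against CON), 1 (OD7 against CON), 18 (OD10 against OD3) and 27 (OD mean against OXA). Limma-trend on FPKM gave 2 for OD7 against CON and 13 for the OD mean against OXA, and a log2 change of 1 gave 0 (OD3), 1 (OD7), 30 (OD mean against OXA) and 0 (against DC). A muscle covariate gave 0 (OD3), 1 (OD7) and 0 (OD mean against OXA). Without libraries high in muscle the counts were 0 (OD3) and 1 (OD7), and FPKM library sizes gave 1 (OD7) and 47 (FLN YF against ICD).

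A nuclear RNA covariate gave 72 (PLN YF against OD), 1 (FLN YF against ICD) and 5 (FLN against PLN). Without the 8 libraries low in nuclear RNA the counts in FLN, each on 1 residual degree of freedom and with ICD as 1 library, were 19 (OD against ICD), 270 (YF against OD), 298 (YF against ICD) and 2 (YF against control), and 0 for FLN against PLN. FLN against PLN gave 0 without the block, within each regimen and without conditions high in muscle. Leaving out 1 library gave 0 to 529 (OXA against CON), 0 to 3 (OD7 against CON), 0 to 1 (OD3 against CON, OD10 against OD7), 0 to 347 and 0 to 2 (OD mean against OXA, DC), 0 to 3 (PLN slope difference), 0 to 202, 1 to 6, 1 to 439 and 0 to 4 (FLN OD against ICD, YF against OD, YF against ICD, slope difference) and 0 to 6 (FLN against PLN). Signs reversed for Acta1 (0.466), Atp2a1 (0.269) and Mybpc2 (0.109) in the OD mean against OXA with a muscle covariate, which removes muscle genes by construction, and for interferon alpha (-0.228) and proliferation (0.216) in FLN against PLN within ICD. Of list calls, 0 held with an estimated correlation and 6 with fry.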

Other observations

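The 3 relations of this part were set before any correlation was computed, though after group levels had been seen, and none was chosen after its own result. Cd8a, which marks cytotoxic T cells, was asked to track the interferon-gamma list across the 20 tumor libraries. Pearson r was 0.805 (permutation p = 2e-05, adjusted p = 3e-05) and rank correlation 0.806 (p = 5e-05, adjusted p = 7.5e-05). It was 0.645 without the 2 libraries farthest from the median of Cd8a, OXA replicate 2 and CON replicate 5, and 0.893 after group means were removed (p = 1e-05, the smallest of 100000 permutations). With the MHC class II list r was 0.891, rank correlation 0.832, 0.783 without those 2 and 0.903 within groups.

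Hypoxia genes served as a contrast: r with Cd8a was -0.0539 (permutation p = 0.822), rank correlation -0.0812 (p = 0.735), -0.288 without the 2 libraries and -0.143 within groups (p = 0.548). Cd8a itself stood at 18.7 ± 10.6 CPM in CON (n = 3) and 40.3 ± 20.5 in OD7 (n = 3), with no call. Cd8a was the only held gene of the CD8 list in tumor, so these relations do not separate CD8 T cells from other immune content. Their source was not tested.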
